A study of Rattus norvegicus with 24 samples.

How the data were processed

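Lung RNA of 24 male Sprague-Dawley rats was measured on 1 array each, in 6 groups of 4 that crossed air or cigarette smoke with air, Iraqi sand or silica. Groups and animal numbers were taken from the sample labels. Per the labels' protocols, the right caudal lobe was kept in an RNA-preserving solution, and RNA was extracted with a phenol reagent and cleaned on silica columns. The deposited values are on the log2 scale, and per the submitters' processing notes they were made with RMA, which corrects the background, normalizes the arrays to the same quantiles and summarizes the probes of a probe set. The version of RMA was not given in the sources used here, and scanner files were not used here. The values run from 2.90 to 15.04, and no quantile differed by more than 0.20 between arrays, as quantile normalization leaves them. RMA forces the arrays to 1 distribution, so a change shared by most genes would be removed, and it compresses the changes of dim probe sets. No date, batch or time of day was in the labels, so none could be entered as a block.

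Of 31099 probe sets, 57 controls were left out. In the platform annotation given, 20826 of the other 31042 had 1 gene symbol, 436 had several and 9780 had none. A gene was represented by its probe set with the highest mean over the 24 arrays among those with exactly 1 symbol, which gave 14217 genes, 4525 of them with more than 1 probe set. The Entrez numbers of 20758 of the probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCr8, and 0 symbols changed on that match. No coordinates are given because the files name no genome build. The 10216 probe sets with several or no symbols were tested apart, with their own adjustment.

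One linear model with 6 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), which left 18 residual degrees of freedom and a median residual standard deviation of 0.153. The 15 comparisons were smoke against air within each particle condition, each particle against air within air and within smoke, each combined exposure against air alone, both interactions, and smoke, Iraqi sand, silica and sand against silica averaged over the other exposure. Tests were two-sided with Benjamini-Hochberg adjustment within a comparison, at an adjusted p under 0.05, with no filter on dim probe sets. As the rats are separate animals, p-values refer to the spread between animals.

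The 29 gene lists held 640 entries, of which 552 matched a measured gene. They cover the AhR response, NRF2 antioxidant genes, cytokines, complement, interferon-stimulated genes, antigen presentation, extracellular matrix, proliferation, the circadian clock, glucocorticoid and metallothionein response, immediate early genes, heat shock, unfolded protein and amino acid stress, and cholesterol biosynthesis. Cell marker lists cover alveolar macrophages, neutrophils, alveolar type 1 and type 2 cells, club and secretory cells, ciliated cells, B and plasma cells, T and NK cells, endothelium, smooth muscle, mast cells and eosinophils, erythroid cells, mesothelium, adipocytes, and cardiac and striated muscle, the last 3 for tissue that can adhere to a lobe. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation and the rotation test fry as alternatives, adjusted over the 29 lists of a comparison. Fry asks whether the genes of a list move 1 way on balance and does not set them against other genes. Counts of members are given over all genes and adjusted over the list alone.

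Named genes followed a rule. In each comparison they were the 10 largest rises and the 10 largest falls past the threshold whose groups did not overlap, or, in averaged comparisons, whose components had the same sign. Up to 4 members of each list with the largest moderated t were added, and in every comparison Cyp1a1, Cyp1b1, Nqo1, Hmox1, Mmp12, Lcn2, Cxcl1, Cxcl2, Ccl2, Il1b, Spp1, S100a9, Scgb1a1, Sftpc and Col1a1. Where no gene passed, the 5 with the smallest p are given as values. Genes outside the rule are said to be so. The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

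The alternatives were eBayes with trend and robust shrinkage, genes at or above the median level, the mean of a gene's probe sets, a change of at least 1.5-fold, only the arrays of the groups compared, array quality weights, centring on array medians, quantile normalization over again, the RNA integrity number as a covariate on 19 arrays, and each rat left out in turn. Leaving out rat 302 from the shared fit, leaving out rats 302, 104 and 604 together, and fitting the same 19 arrays without the covariate were chosen after seeing the data. For each count, other assignments of the same rats to groups were refitted, all 35 for 2 groups of 4 and 100 drawn otherwise. Correlations of effects that share controls were set beside 100 simulated unchanged groups and beside splits of the controls. For shared calls, the splits of the controls were chosen after seeing the data, and so were the list tests with each rat left out or without rats 504 and 605. The fit was tested on simulated data with 200 changed genes among 14217. For smoke without particles limma called 76% of genes changed 1.5-fold and 96% of genes changed 2-fold, with 10 wrong calls, and for smoke on average 92% and 100%, with 9. With no gene changed, it made 0 wrong calls for Iraqi sand without smoke and for the smoke by silica interaction. In these data camera called a raised list of 25 genes and not an unchanged one. This does not test the preset correlation of 0.01, as estimates for the lists ran from 0.0118 (AhR) to 0.757 (ciliated). Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.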

Results

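Gene expression was measured in the right caudal lung lobe of male Sprague-Dawley rats, an outbred laboratory strain, on 24 Affymetrix rat expression arrays, 1 array per rat. The rats formed 6 groups of 4, with every combination of air or cigarette smoke, given nose-only, and air, Iraqi sand or silica, given to the whole body in a chamber. Smoke was set to 0.48 mg of wet total particulate matter per litre for 3 hours a day on 5 days a week, over 5 weeks in the protocol and 6 weeks in the series text. Particles were set to 1 mg per cubic metre for 18 hours a day on 7 days a week over 2 weeks. The series text names 17 rats per group and 102 in all, of which 4 per group are analysed here. Its title asks about combined effects of smoke and inhaled sand. Silica was the other particle, and crystalline silica is known to injure and inflame the lung. The array medians lay between 7.26 and 7.32 on the log2 scale, and RNA integrity numbers, known for 19 arrays, between 8.1 and 9.8. The number of arrays limits the precision of every value.

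In the account of each comparison, changes are log2 differences with their standard errors, for 4 rats per group, and adjusted p-values come from limma over 14217 genes. A named call was kept when each rat of the compared groups was left out in turn, unless rats are named beside it. Of 435 tests of gene lists, 171 passed with the preset correlation between genes, 5 with an estimated one and 15 with the rotation test fry. The 5 belong to the alveolar macrophage and phagocyte list alone. Of the named lists that passed, rats are named where the preset call ended without 1 of them or the mean change of the list moved by more than 1.5 times. With array quality weights 14 of the 15 counts of calls were more than 1.5 times higher, and none was lower by as much. No list past the preset test differed in sign between its median, its mean and its test.

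Marker genes set 3 rats apart from the rest of their groups. Rat 302, of the air and Iraqi sand group, had a mean correlation of 0.944 with the other arrays, and its highest with any array was 0.960 against 0.988 or more for each of the other 23 arrays. In it 235 genes were at least 2-fold higher and 1211 at least 2-fold lower than the mean of its group mates, against a median of 50 such genes over the other rats. The atrial myosin light chain Myl7 stood at 11.51 in rat 302 and at 5.26 ± 0.61 (SD, n = 3) in its group mates, and 15 of 25 cardiac and striated muscle markers were at least 2-fold higher there. Transcripts of airway secretory cells were higher in it too, with Bpifa1 at 12.63 against 6.87 ± 0.16 (SD, n = 3). Rat 104, of the control group, also carried heart muscle transcripts, with Myl7 at 12.04 against 6.69 ± 0.96 (SD, n = 3), and transcripts of airway secretory cells, with Bpifa1 at 11.77 against 6.97 ± 0.06 (SD, n = 3). Rat 604, of the smoke and silica group, was higher in the proliferation marker Mki67, at 8.90 against 6.62 ± 0.27 (SD, n = 3), in the basal cell keratin Krt5, at 8.69 against 5.58 ± 0.11 (SD, n = 3), and in all 40 genes of the proliferation list. Beside the leading counts, counts without rat 302 and without all 3 rats are given. They were chosen after seeing the data, and so were Myl7, Bpifa1, Mki67 and Krt5, after their values were seen.

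**Figure D1:**
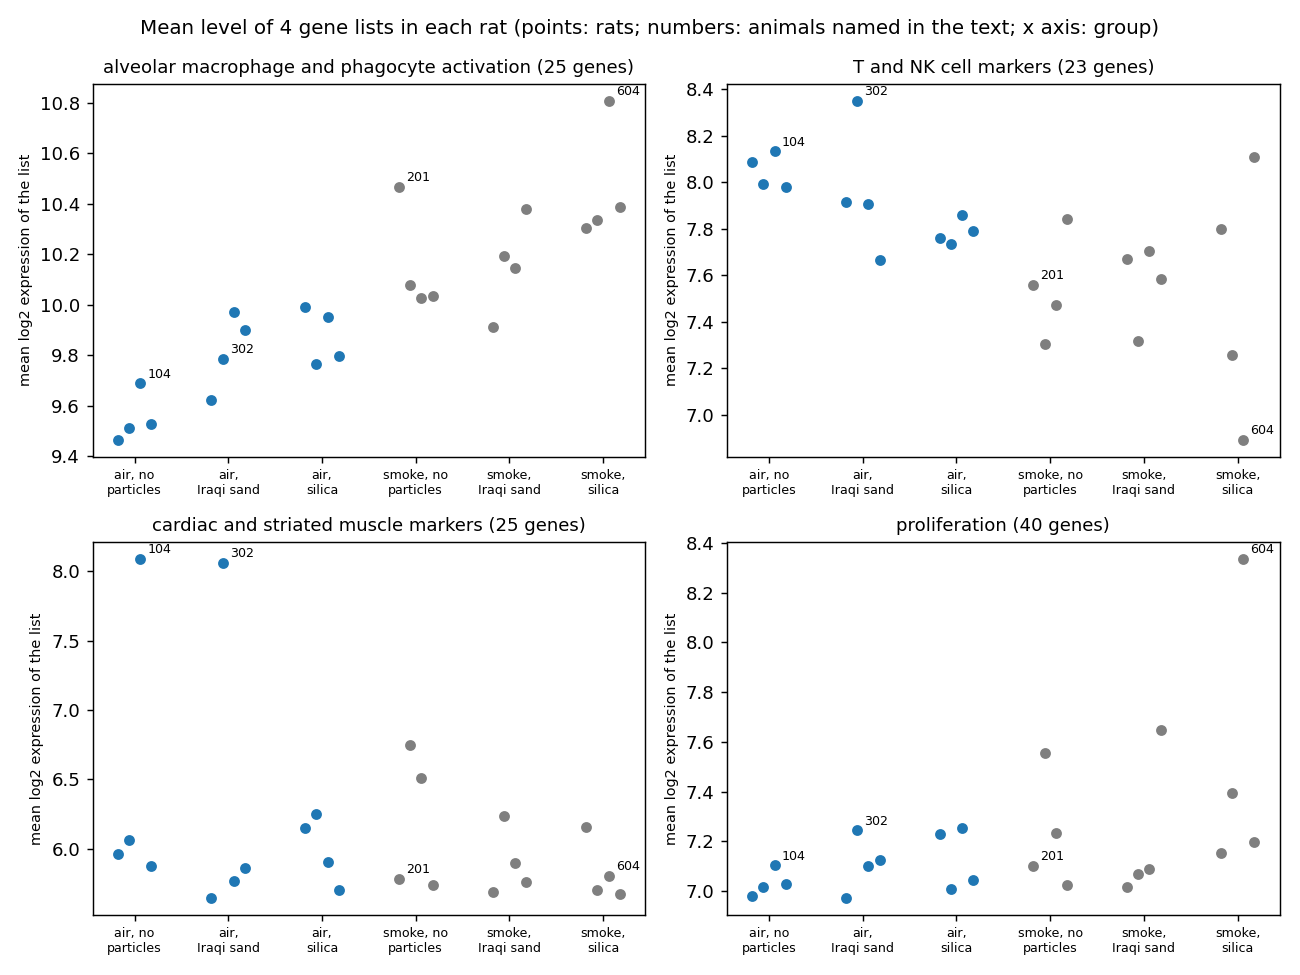
Mean log2 level of the genes of 4 lists (alveolar macrophage and phagocyte activation, T and NK cell markers, cardiac and striated muscle markers, proliferation) in each of the 24 rats, grouped by exposure, with 1 point per rat. Rats 104 and 302 stand at 8.09 and 8.06 for the cardiac list, above the rest of their groups, and rat 604 and rat 201 at 10.8 and 10.5 for the macrophage list.

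Smoke without particles was compared with air alone to describe what smoke by itself did. Genes of macrophages rose. Gpnmb, a glycoprotein of lipid-laden macrophages, rose 2.82-fold (adjusted p = 3.38e-04), the lysosomal membrane protein Cd68 by 1.26 ± 0.19, the galectin Lgals3 by 0.93 ± 0.10 and the lysosomal protease Ctsd by 0.91 ± 0.10. The neutrophil-attracting chemokine Cxcl1 rose by 2.11 ± 0.26, or 4.33-fold (adjusted p = 2.63e-04), together with the chitinase Chia at 1.99 ± 0.35, the chemokine receptor Cxcr1 at 1.35 ± 0.22, the arginine-degrading enzyme Arg1 at 1.35 ± 0.21 and the central complement component C3 at 1.43 ± 0.20. Of the 25 measured genes of the macrophage list 9 rose, or 15 when adjusted over the list alone, and the list rose as a set (adjusted p = 2.06e-21, and adjusted p = 0.0163 with an estimated correlation). Among 35 cytokine, chemokine and inflammasome genes 4 rose, or 5 adjusted over the list alone, including the macrophage growth factor Csf2 at 0.62 ± 0.12 and Ccl3 at 0.80 ± 0.16. The call of Ccl3 ended without rat 102 or rat 201, with an adjusted p of at most 0.0696. That list passed at adjusted p = 6.68e-04, with adjusted p = 0.291 with an estimated correlation.

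Clock genes moved both ways under smoke alone. The repressors Per2, at 1.21 ± 0.22, Cry1, at 0.88 ± 0.16, and Bhlhe41, at 1.03 ± 0.15, rose, and the activator Npas2 fell by 1.36 ± 0.30, a call that ended without rat 102, 103, 201, 204 or 205 (adjusted p up to 0.14). In all 4 of 17 clock genes rose and 1 fell, or 4 and 2 without the 3 rats, and 4 and 2 adjusted over the list alone (list adjusted p = 0.0164, or 0.269 with an estimated correlation). The list call ended without rat 103 (adjusted p = 0.0853). The vascular transcription factor Klf2 fell by 0.96 ± 0.18 and the sulfatase Arsi by 1.04 ± 0.16. None of the 27 NRF2 antioxidant genes passed over all genes, against 3 without rat 302 and 5 without the 3 rats. Adjusted over the list alone 12 rose, and the list passed at adjusted p = 1.15e-10, with adjusted p = 0.224 with an estimated correlation. Rat 203 was higher than its group mates in 24 of the 27, and without it the mean change of the list went from 0.347 to 0.234. List members Gsta3 and Nqo1 stood at 1.10 ± 0.28 and 0.54 ± 0.25 (adjusted p = 0.0747 and 0.465). None of 23 T and NK cell markers passed over all genes either, against 2 that fell without rat 302 and 1 without the 3 rats. Adjusted over the list alone 12 fell, and the list lay lower at adjusted p = 2.91e-11, with adjusted p = 0.246 with an estimated correlation. The aryl hydrocarbon receptor target Cyp1a1, which smoke constituents are known to induce, stood at -0.07 ± 0.32 (adjusted p = 0.992), and 0 of the 9 genes of its list passed in limma over all genes or over the list alone, with 1 that rose without the 3 rats.

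Over all genes, smoke without particles raised 108 and lowered 19, with 1415 genes at an unadjusted p under 0.05. Without rat 302 all 127 were kept among 269, and without the 3 rats 119 among 279. The count fell to 46 without rat 201, whose macrophage list mean of 10.5 lay above the 10.0 of its group mates. It was 57 without rat 102, 69 without rat 103, 79 without rat 105, 75 without rat 203 and 84 without rat 204.

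Smoke under Iraqi sand compared the smoke and Iraqi sand group with the air and Iraqi sand group, which holds rat 302. Among the largest rises of genes whose groups did not overlap were those of the cohesin loader Nipbl by 1.53 ± 0.22, the nuclear receptor Rora by 1.52 ± 0.21, the D-type cyclin Ccnd2 by 1.28 ± 0.19 and the transcription factor Klf13 by 1.25 ± 0.19. The secreted protein Fam3b fell by 1.60 ± 0.25 and the clock repressor Nr1d1 by 1.41 ± 0.22 (adjusted p = 0.00293). Cxcl1, at 1.31 ± 0.26, and Gpnmb, at 0.89 ± 0.19, rose as well, but their calls ended without rat 302 and without rats 402 or 406, and that of Gpnmb also without rats 301 or 404, with adjusted p up to 0.0817 and 0.0878. Only 1 of 25 macrophage genes rose, or 7 adjusted over the list alone, none of them over all genes without rat 302 (list adjusted p = 6.69e-07, or 0.727 with an estimated correlation). Of 17 surfactant and alveolar type 2 markers 2 fell, or 3 with 1 that rose adjusted over the list alone, namely the lipid enzyme Lpcat1, by 0.50 ± 0.11, and the lipid transporter Abca3, by 0.33 ± 0.07. The list did not pass (adjusted p = 0.121, or 0.0082 without rat 302), and both gene calls ended without rats 302, 402, 404, 405 or 406, and that of Abca3 without rat 304, with adjusted p up to 0.0858 and 0.0847. None of 18 genes of cholesterol biosynthesis passed over all genes and 7 fell adjusted over the list alone, with 1 over all genes without rat 302 or without the 3 rats (list adjusted p = 0.00885, or 0.772 with an estimated correlation), with the squalene synthase Fdft1 at -0.48 ± 0.14 (adjusted p = 0.0824). The call of the cholesterol list ended without rat 304 (adjusted p = 0.0869).

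In all, 52 genes rose and 132 fell under smoke with Iraqi sand (2916 at an unadjusted p under 0.05), and 42 rose and 57 fell after quantile normalization over again. Without rat 302 only 73 of the 184 were kept among 92, without the 3 rats 97 among 139, and 0 genes passed in limma on the 8 arrays of these groups alone. The count was 92 without rat 302, 703 without rat 305, 37 without rat 402, 114 without rat 404, 74 without rat 405 and 30 without rat 406.

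Smoke under silica compared the smoke and silica group with the air and silica group. The clock repressor Nr1d1 fell by 1.44 ± 0.22 (adjusted p = 0.0181), the only gene of 14217 to pass, and its call ended without rat 502, 503 or 604 (adjusted p up to 0.151). The macrophage list rose as a set (adjusted p = 1.18e-19, and adjusted p = 0.0242 with an estimated correlation), though 0 of its 25 genes passed over all genes in limma, or 5 without rat 302 and 0 without the 3 rats, and 15 rose adjusted over the list alone. Rat 604 had a macrophage list mean of 10.8 against 10.3 in its group mates. Members of the list stood at 0.97 ± 0.19 for Gpnmb, 0.89 ± 0.19 for Cd68 and 0.47 ± 0.10 for Lgals3, with adjusted p of 0.078, 0.0823 and 0.0823. The bone and macrophage protease Ctsk stood at 1.18 ± 0.22 (adjusted p = 0.0732). The NRF2 list passed at adjusted p = 3.38e-09, with adjusted p = 0.376 with an estimated correlation, and 0 of its 27 genes passed over the list alone, with the glutathione synthesis genes Gclm and Gclc at 0.63 ± 0.19 and 0.40 ± 0.13. Rat 604 was higher than its group mates in 22 of the 27, and without it the mean change of the list went from 0.284 to 0.151. All 40 genes of the proliferation list were higher in rat 604 of this comparison than in its group mates, and that list lay higher at adjusted p = 9.34e-13, with adjusted p = 0.457 with an estimated correlation and 0 genes past either threshold in limma. Without that rat its mean change went from 0.386 to 0.114. At an unadjusted p under 0.05 there were 1161 genes. Without rat 302, which is in neither group but enters the shared spread, 61 genes passed, and without the 3 rats 3, Nr1d1 among them both times. Left out singly, rats gave 16 without rat 501, 0 without rat 502, 503 or 604, 2 without rat 602 and 3 without rat 605.

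Averaged over the 3 particle conditions, the 12 smoke rats were compared with the 12 air rats. Among the largest rises were those of the gel-forming mucin Muc5b by 1.99 ± 0.50, the water channel Aqp3 by 1.95 ± 0.38, the disulfide isomerase of mucin folding Agr2 by 1.66 ± 0.37 and the acute phase protein Saa3 by 1.57 ± 0.37 (adjusted p = 0.0215, 0.00381, 0.0105 and 0.0138). Of 17 club and secretory airway markers 4 rose and 1 fell, or 6 and 2 adjusted over the list alone (list adjusted p = 0.0478, or 0.453 with an estimated correlation). The list call ended without each of rats 103, 105, 203, 204, 301, 304, 305, 404, 405, 504, 602 and 603 (adjusted p up to 0.113). The club cell oxidase Cyp4b1 was the one that fell, by 0.71 ± 0.14, and the secretoglobin Scgb1a1 stood at -0.06 ± 0.04 (adjusted p = 0.312). Rats 302 and 104, both among the air rats, were at least 2-fold above their group mates in 7 and 6 of these 17 genes, and smoke rats 203, 204 and 604 in 5, 4 and 4. Without rat 302, 6 rose and 1 fell, and without the 3 rats 6 and 2. Among 13 markers of ciliated cells 1 rose, the dynein light chain Dynlrb2 by 0.65 ± 0.17, or 4 adjusted over the list alone (list adjusted p = 1.56e-04, or 0.453 with an estimated correlation). Smoke rats 203 and 204 were higher than their group mates in all 13 of these markers and air rat 302 in 11, and without rat 302, 2 rose. The call of Dynlrb2 ended without rat 203, 204, 406, 504, 602 or 603, with adjusted p up to 0.0583.

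Macrophage genes rose broadly, 14 of 25 over all genes and 21 adjusted over the list alone, and none fell (list adjusted p = 6.80e-21, and adjusted p = 0.0183 with an estimated correlation). Gpnmb rose by 1.12 ± 0.11, Cd68 by 0.94 ± 0.11, Ctsd by 0.59 ± 0.06 and Lgals3 by 0.54 ± 0.06, each in both the smoke alone and the averaged comparison, and the elastase Mmp12 by 1.18 ± 0.28. Without rat 302, 15 of the 25 rose, and without the 3 rats 12. The secreted phosphoprotein Spp1 stood at 1.47 ± 0.49 (adjusted p = 0.0745). Of 35 cytokine genes 7 rose and 1 fell, or 11 and 3 adjusted over the list alone (list adjusted p = 1.56e-04, or 0.332 with an estimated correlation). Cxcl1 rose by 1.28 ± 0.15, Cxcl2 by 0.73 ± 0.15 and Ccl3 by 0.48 ± 0.09. The gene that fell was Ccl24, by 0.30 ± 0.08, which was chosen after its values were seen. Its call ended without rat 503 or 603 (adjusted p up to 0.0506). Il1b and Ccl2 stood at 0.54 ± 0.21 and 0.37 ± 0.35 (adjusted p = 0.114 and 0.54). The neutrophil list had 2 of 12 genes that rose, S100a9 by 1.35 ± 0.23 and Cxcr1 by 1.00 ± 0.13, or 4 adjusted over the list alone (list adjusted p = 7.57e-05, or 0.332 with an estimated correlation). Smoke rat 201 had a neutrophil list mean of 8.95 against 7.68 in its group mates. Without rat 302, 3 of the 12 rose, and without the 3 rats 2.

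Antioxidant genes of the NRF2 list rose in 6 of 27 cases. Without rat 302, 11 rose and 1 fell, and without the 3 rats 10 and 1. Adjusted over the list alone 15 rose and 1 fell (list adjusted p = 9.06e-09, or 0.332 with an estimated correlation). Smoke rats 203 and 604 were higher than their group mates in 24 and 22 of the 27, and the mean change of the list went from 0.228 to 0.190 without rat 203 and 0.183 without rat 604. The subunits of glutamate-cysteine ligase, the limiting enzyme of glutathione synthesis, rose by 0.39 ± 0.07 for Gclc and 0.45 ± 0.11 for Gclm, the glutathione transferase Gsta3 by 0.82 ± 0.16 and the pentose phosphate enzyme Taldo1 by 0.24 ± 0.06. Nqo1 and Hmox1 stood at 0.39 ± 0.14 and 0.20 ± 0.13 (adjusted p = 0.103 and 0.353). For the aryl hydrocarbon receptor list 0 of 9 genes passed in limma over all genes or over the list alone, and 2 rose without the 3 rats (list adjusted p = 0.0935), with Cyp1a1 at -0.29 ± 0.19 and Cyp1b1 at 0.23 ± 0.14.

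Some lymphocyte markers fell with smoke. Of 23 T and NK cell markers 8 fell and none rose, or 14 adjusted over the list alone (list adjusted p = 9.06e-09, or 0.332 with an estimated correlation): the receptor subunits Cd3d and Cd3g by 0.64 ± 0.13 and by 0.64 ± 0.14, the surface protein Cd5 by 0.69 ± 0.15 and the adhesion molecule Cd2 by 0.43 ± 0.09. Air rat 302 lay at a median of 0.56 above its group mates over these genes, with 20 of 23 higher, and smoke rat 604 at -0.88, with 2 of 23 higher. Without rat 302, 8 of the 23 fell, and 6 without the 3 rats. Of 12 B and plasma cell markers 2 fell, or 5 adjusted over the list alone (list adjusted p = 0.00949, or 0.46 with an estimated correlation), including the B cell coactivator Pou2af1 by 0.62 ± 0.15. All 12 of these markers were higher in rat 302 than in its group mates, and without the 3 rats 1 fell. The thin epithelial cells of the alveolus had 3 of 13 markers that fell, Ager by 0.20 ± 0.05, the water channel Aqp5 by 0.24 ± 0.05 and Gprc5a by 0.26 ± 0.05, or 6 without rat 302, 4 without the 3 rats and 4 adjusted over the list alone (list adjusted p = 0.00258, or 0.453 with an estimated correlation). Of 17 surfactant and type 2 markers 1 rose, the chitinase Chia by 1.51 ± 0.20, and 1 fell, Lpcat1 by 0.40 ± 0.06, or 1 and 2 without rat 302, 1 and 3 without the 3 rats, and 1 and 3 adjusted over the list alone (list adjusted p = 0.304), and surfactant protein Sftpc stood at -0.02 ± 0.03 (adjusted p = 0.605). Endothelial markers fell in 2 of 19 cases, or 3 without rat 302, 3 without the 3 rats and 5 adjusted over the list alone, among them the tight junction protein Cldn5 by 0.36 ± 0.09 (list adjusted p = 0.00392, or 0.453 with an estimated correlation). Smoke rat 604 lay at a median of -0.37 from its group mates over the endothelial markers.

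Clock genes split into 4 that rose and 4 that fell of 17, over all genes and adjusted over the list alone. Cry1 rose by 0.75 ± 0.09, Per2 by 0.85 ± 0.13 and Bhlhe41 by 0.81 ± 0.09, and all 12 smoke rats lay beyond every air rat in Cry1 and in Bhlhe41. Nr1d1 fell by 1.12 ± 0.12 and Npas2 by 0.92 ± 0.18 (adjusted p = 2.23e-05 and 0.00314). With members that moved both ways, the list did not pass (adjusted p = 0.329). The complement list, at adjusted p = 0.00392 with adjusted p = 0.332 with an estimated correlation, had 1 of 11 genes that rose, C3 by 0.62 ± 0.12, over all genes and over the list alone, and 3 without rat 302.

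Over all genes, smoke raised 382 and lowered 526 on average (3482 at an unadjusted p under 0.05), and 119 of the 908 changed by at least 1.5-fold. Without rat 302, 898 were kept among 1463, and without the 3 rats 748 among 1182. The count was 586 without rat 203.

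**Figure D2:**
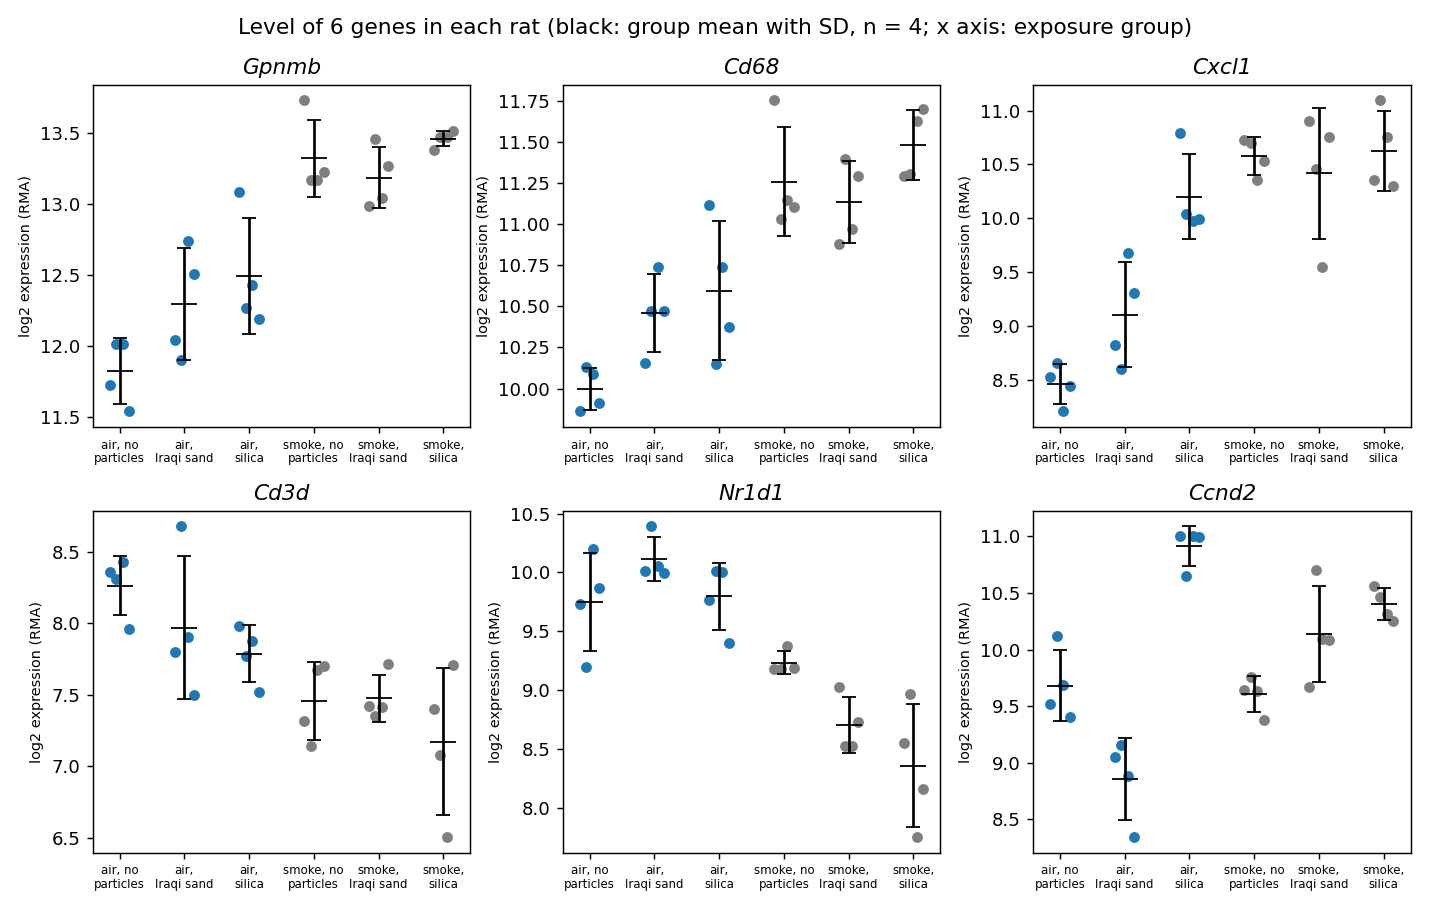
Log2 level of Gpnmb, Cd68, Cxcl1, Cd3d, Nr1d1 and Ccnd2 in each of the 24 rats, grouped by exposure, with 1 point per rat and the mean and SD of each group of 4. Gpnmb and Cd68 lie higher and Nr1d1 lower in the smoke groups, and Ccnd2 is highest in the air and silica group, at 10.91 ± 0.18 (SD, n = 4).

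Iraqi sand without smoke was compared with air alone. The scaffold protein Card14, at 0.77 ± 0.12, and the lipid acyltransferase Lpgat1, at 0.60 ± 0.10, rose, and the open reading frame C11h21orf91, by 1.08 ± 0.18, and the transcription factor Klf4, by 0.60 ± 0.10, fell, the only 4 genes to pass (adjusted p between 0.0243 and 0.0381, 1456 genes at an unadjusted p under 0.05). Each of the 4 calls ended without rat 104, 304 or 305, and some without rats 102, 103, 105 or 302, with adjusted p up to 0.164 for Klf4 and 0.122 for the others. The haem-degrading enzyme Hmox1 stood at 0.99 ± 0.23 and C3 at 0.98 ± 0.20 (adjusted p = 0.105 and 0.0824). Of 17 surfactant and type 2 markers none passed over all genes and 4 rose adjusted over the list alone, with the surfactant-processing protease Napsa at 0.38 ± 0.07 (adjusted p = 0.0545), and the list lay higher at adjusted p = 1.19e-04, with adjusted p = 0.558 with an estimated correlation. Control rat 104 was lower than its group mates in 16 of these 17 genes, and without it the mean change went from 0.202 to 0.121 (adjusted p = 0.0269). Among 25 macrophage genes 3 rose adjusted over the list alone and none over all genes, with Lgals3 and Ctsd at 0.48 ± 0.10 and 0.47 ± 0.10 (list adjusted p = 1.66e-04, or 0.558 with an estimated correlation, and 0.0586 without rat 304). Cxcl1 stood at 0.64 ± 0.26 (adjusted p = 0.429). Rats 104 and 302, a control and a sand rat, both carried the heart muscle transcripts given for them, and without rat 302, 2 of the 4 calls were kept among 4, and without the 3 rats 2 among 5. Left out singly, rats moved the count to 1 without rat 102 or 103, 0 without rat 104 or 304, 30 without rat 301 and 2 without rat 305.

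Silica without smoke raised 20 genes and lowered none (711 at an unadjusted p under 0.05). Among them Cxcl1 rose by 1.74 ± 0.26, or 3.33-fold, the complement component C3 by 1.25 ± 0.20 and the complement regulator C4bpa by 1.15 ± 0.20 (adjusted p = 0.0067, 0.00746 and 0.0161). The clock and activation repressor Bhlhe40 rose by 1.73 ± 0.20 (adjusted p = 2.15e-04) and Ccnd2 by 1.23 ± 0.19. Of 35 cytokine genes 3 rose, or 6 adjusted over the list alone, with Ccl3 at 0.92 ± 0.16 and Csf2 at 0.66 ± 0.12 (list adjusted p = 5.42e-05, or 0.322 with an estimated correlation). The calls of C4bpa, Ccl3 and Csf2 ended without rat 105 or 501, and those of C4bpa and Csf2 also without rat 104, and C4bpa without rat 503, with adjusted p up to 0.0963, 0.0708 and 0.0904. None of 25 macrophage genes passed over all genes and 7 rose adjusted over the list alone (list adjusted p = 2.07e-12, or 0.076 with an estimated correlation), with Gpnmb at 0.67 ± 0.19 and Mmp12 at 1.06 ± 0.48 (adjusted p = 0.394 and 0.972). The surfactant and type 2 list lay higher at adjusted p = 1.07e-08, with adjusted p = 0.076 with an estimated correlation, and 1 of its 17 genes rose adjusted over the list alone. Without control rat 104, lower than its group mates in 16 of the 17, the mean change went from 0.195 to 0.114. Of the 20 calls, 20 were kept without rat 302 among 42 and 17 without the 3 rats among 31. On the 8 arrays of these groups alone 2 genes passed. With 1 rat left out the count was 9 without rat 104, 8 without rat 105 or 501 and 10 without rat 503.

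Particles were also compared within the smoke rats. Iraqi sand under smoke raised Cped1, a gene of the cadherin-like and PC-esterase domain family, by 0.79 ± 0.13 and the secretory vesicle protein Rab27b by 0.62 ± 0.10 (both adjusted p = 0.038), and 544 genes had an unadjusted p under 0.05. Both calls ended without each of rats 201, 203, 204, 205, 402, 404 and 406, with adjusted p up to 0.314. Silica under smoke raised Cped1 by 1.08 ± 0.13 (adjusted p = 6.19e-04) and the transcription factor Arid5b by 0.59 ± 0.08 (adjusted p = 0.00537), with 1179 genes at an unadjusted p under 0.05. Its endothelial list lay lower at adjusted p = 1.17e-05, with adjusted p = 0.636 with an estimated correlation, and 6 of 19 genes fell adjusted over the list alone. Rat 604 lay at a median of -0.37 from its group mates over these genes, with 4 at least 2-fold lower, and had the highest macrophage list mean of its group, 10.8. The macrophage list lay higher with silica under smoke at adjusted p = 9.11e-05, with adjusted p = 0.636 with an estimated correlation, and its mean change went from 0.307 to 0.191 without rat 604. Proliferation genes, all higher in rat 604 than in its group mates, lay higher at adjusted p = 2.35e-08, with adjusted p = 0.636 with an estimated correlation, but the list call ended without that rat (adjusted p = 0.318), when the mean change went from 0.291 to 0.018. Without rat 302, 66 genes passed for silica under smoke, and without the 3 rats 14. For Iraqi sand under smoke these counts were 5 and 6, and both pairs of calls were kept each time, while without rat 405 the sand count was 7.

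Averaged over air and smoke, silica raised 40 genes and lowered 9, and Iraqi sand had 0 calls in limma, against 843 and 89 calls with array quality weights. The leading genes of silica were Bhlhe40, which rose by 1.16 ± 0.14, Ccnd2, by 1.02 ± 0.13, Cped1, by 0.92 ± 0.09, and the transcription factor Nfix, by 0.72 ± 0.10 (adjusted p = 1.70e-04, 6.88e-04, 2.64e-05 and 0.00103, n = 8 rats against 8). Of 35 cytokine genes 2 rose, or 4 without rat 302 and 4 adjusted over the list alone, with Ccl3 at 0.64 ± 0.11 (list adjusted p = 1.43e-04, or 0.422 with an estimated correlation). None of 25 macrophage genes passed over all genes, against 2 without rat 302 and 2 without the 3 rats. Of them 9 rose adjusted over the list alone (list adjusted p = 9.06e-11, or 0.245 with an estimated correlation). None of 19 endothelial markers passed, against 2 that fell without rat 302 and 1 without the 3 rats. Of these markers 5 fell adjusted over the list alone (list adjusted p = 3.13e-07, or 0.422 with an estimated correlation). Rat 604 was at least 2-fold below its group mates in 4 of the 19, and without it the mean change went from -0.243 to -0.200. Of 13 ciliated cell markers, all with a negative change, 1 fell adjusted over the list alone and 1 over all genes without rat 302 (list adjusted p = 0.00137, or 0.738 with an estimated correlation). Silica rats 504 and 605 had the lowest ciliated list means of their groups, 8.39 and 8.37, and smoke rat 203 the highest of its group, 10.0. The mean change went from -0.260 to -0.165 without rat 203, to -0.141 without rat 605 (adjusted p = 0.088) and to -0.068 without rats 504 and 605 (adjusted p = 0.417). The 40 proliferation genes, all higher in rat 604 than in its group mates, lay higher as a set at adjusted p = 3.13e-07, with adjusted p = 0.738 with an estimated correlation, and their mean change went from 0.196 to 0.060 without that rat. The immediate early transcription factor Egr2 rose by 0.63 ± 0.11, and the bone mineralization phosphatase Phospho1 fell by 0.54 ± 0.09. For silica 1664 genes had an unadjusted p under 0.05, and 49 of the 49 calls were kept without rat 302 among 542 and 48 without the 3 rats among 172. The silica count was 27 without rat 102 or 204, 28 without rat 503 and 30 without rat 205. For Iraqi sand limma called 0 genes on average, with 742 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0554, for the kinase Prkce at -0.60 ± 0.10. Klf4, Rab27b, the epithelial transcription factor Bnc1 and the lactate transporter Slc16a1 followed, at -0.42 ± 0.07, 0.39 ± 0.07, 0.63 ± 0.12 and 0.38 ± 0.08. For sand the count was 8 without the 3 rats, and 4 without rat 301, 5 without rat 302, 6 without rat 305 and 1 without rat 203 or 404.

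Iraqi sand and silica were set against each other over both smoke conditions. Of 17 genes that differed 4 were higher with sand and 13 with silica (1741 at an unadjusted p under 0.05), and after median centring 2 and 14. Ccnd2 was lower with sand, at -1.16 ± 0.13 (adjusted p = 3.16e-04), as were Cped1, at -0.74 ± 0.09, the energy-sensing kinase subunit Prkaa2, at -0.76 ± 0.13, C11h21orf91, at -0.78 ± 0.13, and the syntenin relative Sdcbp2, at -0.58 ± 0.09. Without smoke the differences were -2.06 for Ccnd2, -1.18 for Cped1, -1.29 for Prkaa2, -1.37 for C11h21orf91 and -0.58 for Sdcbp2, and under smoke -0.26, -0.30, -0.23, -0.18 and -0.57 in the same order. Whether the difference itself depended on smoke was not tested. Group means of Ccnd2 were 9.68 ± 0.31 in controls, 8.86 ± 0.36 with sand and 10.91 ± 0.18 with silica (SD, n = 4), and 9.60 ± 0.16, 10.14 ± 0.43 and 10.40 ± 0.14 in the corresponding smoke groups (SD, n = 4). The semaphorin Sema4d was higher with sand, by 0.50 ± 0.09, and its call ended without rats 402, 405, 406, 501, 502, 503, 504, 602, 603 or 604, with adjusted p up to 0.1. No list gene passed over all genes. The macrophage list lay lower with sand at adjusted p = 4.95e-04 and the proliferation list at 5.22e-06, with adjusted p = 0.97 with an estimated correlation for both. Rat 604, of the silica side, had the highest macrophage list mean of its group and was higher than its group mates in all 40 proliferation genes. Without it the proliferation call ended (adjusted p = 0.058), and the mean change went from -0.169 to -0.032. Of the 17 genes 14 were kept without rat 302 among 25 and 11 without the 3 rats among 24. With 1 rat left out it was 27 without rat 301, 28 without rat 304, 9 without rat 501 or 406, 10 without rat 502, 504, 402 or 604 and 7 without rat 503, 405, 602 or 603. On the 19 arrays with an RNA integrity number 2 genes passed, and 0 with that number as a covariate.

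Smoke and particles together were compared with air alone. Smoke with Iraqi sand raised 91 genes and lowered 48 (1552 at an unadjusted p under 0.05), among them Cxcl1, by 1.95 ± 0.26, Chia, by 1.90 ± 0.35, Cxcr1, by 1.63 ± 0.22, Cxcl2, by 1.45 ± 0.26, and Gpnmb, by 1.36 ± 0.19. Klf2 fell by 1.15 ± 0.18 and Klf4 by 0.72 ± 0.10. Of 25 macrophage genes 6 rose, or 18 adjusted over the list alone (list adjusted p = 2.12e-21, and adjusted p = 0.0164 with an estimated correlation), with the lipid exporter Abcg1 at 0.78 ± 0.13. Cytokine genes rose in 6 of 35 cases, or 9 with 1 that fell adjusted over the list alone (list adjusted p = 1.84e-05, or 0.317 with an estimated correlation). All 139 calls were kept without rat 302 among 564, and 133 without the 3 rats among 376. Singly left out, rats gave 53 without rat 102, 75 without rat 103, 91 without rat 104 or 105, 86 without rat 402, 82 without rat 404 and 54 without rat 406.

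Smoke with silica raised 311 genes and lowered 225 (2626 at an unadjusted p under 0.05). Macrophage genes rose again, Mmp12 by 2.46 ± 0.48, or 5.5-fold, Gpnmb by 1.63 ± 0.19 and Cd68 by 1.49 ± 0.19, beside Arg1 by 1.75 ± 0.21, Cxcl1 by 2.16 ± 0.26 and the resistin-like protein Retnla, whose call ended without the 3 rats, by 2.92 ± 0.61 (adjusted p = 0.00565, 5.11e-05, 8.59e-05, 5.41e-05, 6.12e-05 and 0.00878). Of 25 macrophage genes 15 rose, or 21 adjusted over the list alone (list adjusted p = 9.93e-25, and adjusted p = 0.00812 with an estimated correlation), and 13 without the 3 rats. Of 27 NRF2 genes 8 rose, or 12 adjusted over the list alone, with the sulfiredoxin Srxn1 at 1.09 ± 0.23 (list adjusted p = 2.44e-11, or 0.242 with an estimated correlation). The call of Srxn1 ended without rat 604 (adjusted p = 0.0591). In the list 12 of the 27 rose without rat 302 and 3 without the 3 rats. T and NK cell markers fell in 5 of 23 cases, or 9 adjusted over the list alone, where Cd3d fell by 1.09 ± 0.23 (list adjusted p = 7.02e-08, or 0.517 with an estimated correlation). Rat 604 was at least 2-fold below its group mates in 8 of the 23, and without it the mean change of the list went from -0.534 to -0.327. Without rat 302, 9 of these fell, and 3 without the 3 rats. Endothelial markers fell in 3 of 19 cases, or 6 without rat 302, 3 without the 3 rats and 11 adjusted over the list alone, where Cldn5 fell by 0.76 ± 0.15 (list adjusted p = 1.51e-07, or 0.275 with an estimated correlation). Over these genes rat 604 lay at a median of -0.37 from its group mates, with 4 at least 2-fold lower. Proliferation genes rose in 2 of 40 cases, or 19 adjusted over the list alone (list adjusted p = 2.17e-12, or 0.517 with an estimated correlation). Without rat 302, 8 rose, while 0 passed in limma without the 3 rats, rat 604 among them, and without rat 604 the mean change went from 0.488 to 0.216. All 536 calls were kept without rat 302 among 1777, and 356 without the 3 rats among 586. With single rats left out it was 259 without rat 102, 284 without rat 103, 291 without rat 104, 323 without rat 603 and 200 without rat 604.

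**Figure D3:**
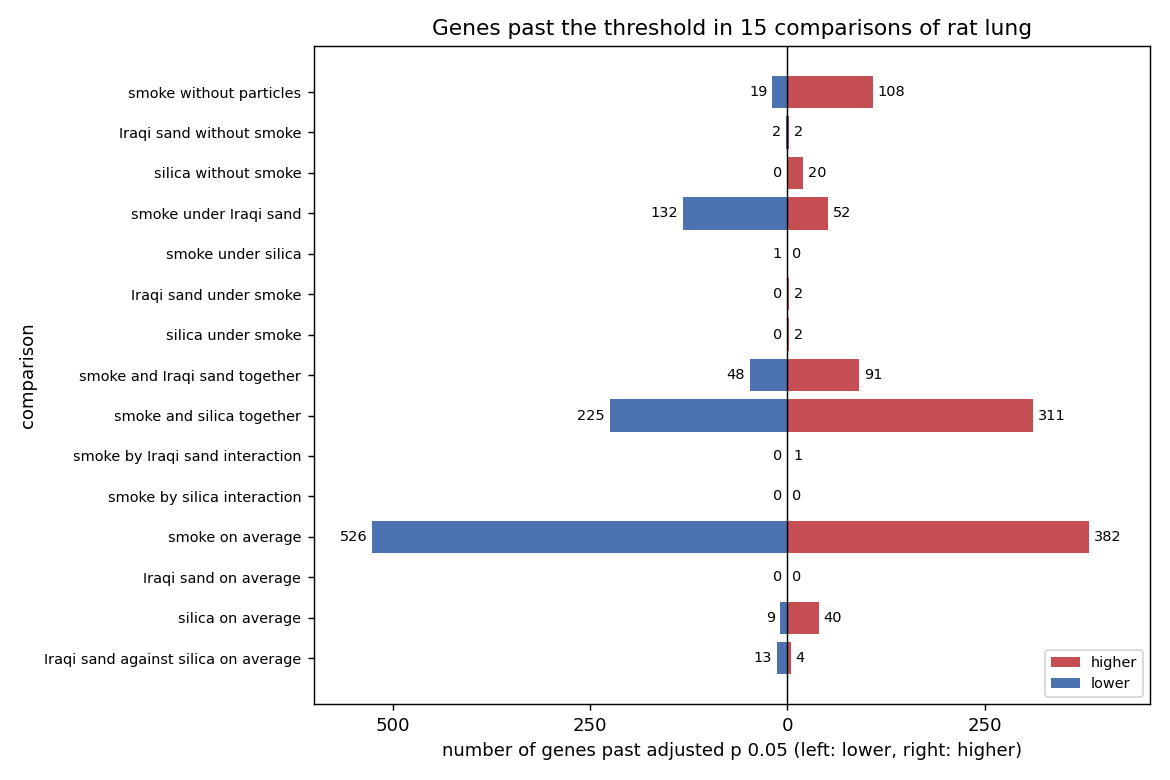
Number of genes higher and lower at an adjusted p under 0.05 (limma) in each of the 15 comparisons, as bars from 0. Smoke on average has the longest bars, with 382 and 526 genes, smoke with silica has 311 and 225, and the smoke by silica interaction has 0.

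Whether smoke and particles acted beyond the sum of each was tested by the interaction. For smoke and Iraqi sand 1 gene passed, Cped1, whose smoke effect was higher with sand by 1.21 ± 0.18 (adjusted p = 0.0251, 1257 genes at an unadjusted p under 0.05). Its group means were 8.21 ± 0.14 in controls, 7.79 ± 0.26 with sand, 7.69 ± 0.12 with smoke and 8.48 ± 0.16 with both (SD, n = 4). The count was 5 without rat 301, 2 without rat 302 and 3 without rat 405, and the call ended without rat 102, 103, 203, 204, 205, 305, 402 or 404, with adjusted p up to 0.104. For smoke and silica limma called 0 genes, with 318 at an unadjusted p under 0.05, and the smallest p-values belonged to C3, Cxcl1, Card14, Bhlhe40 and the nucleotidyltransferase Tent5b, at -1.35 ± 0.28, -1.69 ± 0.37, -0.75 ± 0.17, -1.14 ± 0.28 and -1.36 ± 0.33, each with an adjusted p over 0.99. In the smoke by silica interaction the surfactant list lay lower at adjusted p = 2.78e-07 and the interferon list higher at adjusted p = 2.78e-07, with adjusted p = 0.112 and adjusted p = 0.357 with an estimated correlation. Without control rat 104, lower than its group mates in 16 of the 17 surfactant genes, the mean interaction of that list went from -0.199 to -0.119. Smoke rat 204 was higher than its group mates in 1 of the 24 interferon genes, and without it the mean interaction of the interferon list went from 0.345 to 0.253. For smoke and sand the smooth muscle list lay higher at adjusted p = 3.11e-04, with adjusted p = 0.821 with an estimated correlation, and rat 302 lay at a median of 0.94 above its group mates over its 13 genes. Without rat 406 the mean interaction of that list went from 0.409 to 0.204. In none of these lists did a gene pass over all genes, and 3 surfactant genes fell in the interaction with sand adjusted over the list alone.

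Across genes, which are not independent replicates, the smoke effect without particles correlated at r = 0.43 (Spearman 0.31) with that under Iraqi sand and at r = 0.62 (0.50) with that under silica, and the latter effects at r = 0.47 (0.40). These 3 comparisons share no array. Of the 127 genes called for smoke without particles 112 had the same sign under sand, of which 14 passed there against 1.64 for independent lists, and 123 had it under silica, of which 0 passed in limma, where 1161 genes had an unadjusted p under 0.05. The effects of sand and silica share their controls, and without smoke they correlated at r = 0.31 against a mean of 0.45 and a range of -0.35 to 0.89 for simulated unchanged groups. Without rat 302 this r was 0.619, without rat 304 0.151, without rat 305 0.186 and without the 3 rats 0.549. Their covariance was 0.00899 against a simulated 0.0122, and r was 0.005 over splits of the controls. Under smoke r was 0.55, the covariance 0.0131 and the split value 0.12. Of the 20 genes raised by silica without smoke 18 had the same sign under smoke and 2 passed there. Of the 4 genes changed by Iraqi sand without smoke 2 had the same sign under smoke and 0 passed there in limma. In that comparison 544 genes had an unadjusted p under 0.05, fewer than chance alone would give.

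Calls against the air controls were shared between exposures. Smoke alone and smoke with silica both raised 104 genes and both lowered 17, with 2.36 and 0.301 for independent lists. Smoke alone and smoke with Iraqi sand both raised 65 and lowered 13, with 0.691 and 0.0641 for independent lists, and both combined exposures raised 83 and lowered 30 in common, with 1.99 and 0.760. Smoke alone and silica alone both raised 10 genes, with 0.152 for independent lists, and silica alone and smoke with silica 19, with 0.438. Groups simulated without change against shared controls had a median of 0 calls in limma, so their 0 shared calls leave the overlap of called genes untested. With the controls split 2 and 2, which also lowers the calls, smoke alone and smoke with silica shared 12 to 32 raised genes over 6 splits, smoke alone and smoke with sand 7 to 11, and the combined exposures 13 to 26. For smoke alone and silica alone it was 0 to 2, and for silica alone and smoke with silica 1 to 7. Part of each overlap may come from the shared control rats.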

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

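Chosen only after the result was seen were the tests of heart muscle, degraded RNA and swapped labels for rat 302, of the time of day for the clock genes, and of RNA integrity, faulty probe sets and transcript loss for sand against silica. The screen for single rats covered the array correlations, the 29 list means and the 6 plotted genes in each group, 216 sets of 4 rats. A rat was singled out when its gap to the nearest other rat, as a share of the range of its group, passed Dixon's 95% limit. Chance does this in about 1 of 20 groups, or 10.8 here, and 19 were found.

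Rat 302 of the air and Iraqi sand group was singled out by its mean correlation of 0.944 with the other arrays, its cardiac list mean of 8.06 against 5.76 in its group mates, its B and plasma cell list mean of 8.84, and Nr1d1 at 10.39. Heart muscle in the lung piece may explain its higher cardiac genes, whose median over the 25 listed lay 2.33 above the other 3 rats, with Myl7 at 11.51 and Myh6 at 11.06. It leaves others of its 235 higher genes unexplained, such as the airway secretory genes Bpifa1, higher by 5.76, Scgb3a1, by 3.51, and Muc5b, by 2.23, and all 12 B and plasma cell markers were higher as well. The source of these was not tested. For its 1211 lower genes, dilution by another tissue stays open. Surfactant and type 2 genes lay at a median of -0.0170 on the log2 scale, but type 1 markers at -0.24. Its best correlation with any array, 0.960 with control rat 104, lay below those of all others. The 4 arrays with a lower RNA integrity number than its 8.8 had a higher best correlation. Its low correlations had singled it out, which fixed both outcomes in advance. Dilution, degraded RNA, a fault of this array or its labelling reaction, an outside sample or, beside another fault, an exchanged label may remain. No biological explanation was tested.

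Clock genes differed between the 12 smoke and the 12 air rats, with 8 of 17 called on average. The pattern does not rest on rats 302, 104 and 604, since 8 of these were called in the same direction without them. Smoke rats collected at another time of day than air rats may explain it, as may an effect of smoke. Air rats had nose-only exposure to air on the same schedule, so the nose-only procedure by itself is shared by both. A shift in time of day would move the same genes 1 way in every particle condition, and 1 of the 8 did not: Bhlhe40 stood at 0.94 without particles, 0.55 under sand and -0.19 under silica. The labels give no collection time, so time of day and exposure cannot be told apart.

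Iraqi sand and silica rats differed in 17 genes and in 122 of the 10216 probe sets with several or no symbols, 1.19% against 0.120% of the named genes. A faulty probe set per gene is excluded for 5 of the 8 genes with other probe sets, where another went the same way at an unadjusted p under 0.05, and stays open for the other 12 genes and the probe sets with several or no symbols. RNA integrity is excluded as the whole cause in the 17 genes: the median size of the difference was 0.472 on the 19 arrays and 0.459 with the number as a covariate, where the calls went from 2 to 0 at almost the same size (Ccnd2 at -1.11 with adjusted p = 0.0476, then -1.15 with adjusted p = 0.119), with less precision from a further coefficient. The values argue against a lesser degree of the transcript loss of rat 302 in other rats as the cause. Without that rat its 1211 lower genes stood at a median of -0.00982 (SD 0.108) against the 0.456 to be explained. Its 850 lower probe sets with several or no symbols stood at 0.0154 (SD 0.148) against 0.409. The bound of 1 SD behind this replaced, after the value for the genes was seen, one set before, by which a median of 0 or higher would exclude the loss and -0.00982, with 34 of 100 exchanges of rats as low, decided nothing. A batch effect may remain, as no batch was given, or a particle difference as the biological explanation. Neither was tested.

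Other rats were singled out as follows. Rat 104 of the controls had a mean correlation of 0.982 and list means of 8.09 for cardiac, 7.47 for adipocyte and 9.89 for club and secretory markers. Rat 604 of the smoke and silica group had a mean correlation of 0.980 and a macrophage list mean of 10.8. In the smoke group, rat 201 had Cd68 at 11.75, Gpnmb at 13.73 and list means of 10.5 for macrophage and 8.95 for neutrophil markers, and rat 204 had Nr1d1 at 9.38. Rat 406 of the smoke and Iraqi sand group had list means of 8.81 for immediate early genes and 7.65 for proliferation. In the air and silica group, rat 501 had Cxcl1 at 10.79 and rat 502 had Ccnd2 at 10.65.

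The smoke effect on Cped1 was higher under Iraqi sand than without particles by 1.21 ± 0.18 (adjusted p = 0.0251, limma interaction), the only gene whose smoke effect passed a test of difference between particle conditions. In probe sets with several or no symbols, tested apart from the named genes and counted by probe set, more calls were found than among named genes in 10 comparisons. They numbered 9 for Iraqi sand and 46 for silica without smoke, 274 for smoke under sand, 57 for sand and 16 for silica under smoke, 168 for smoke with sand, 40 for the smoke by sand interaction, 10 for sand and 146 for silica on average, and 122 for sand against silica.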

How the results depend on the processing

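The fits without rat 302, without the 3 rats and on 19 arrays without a covariate were chosen after seeing the data. No paired analysis was possible because the groups share no animal numbers. Of 291 gene results 239 passed the threshold, 148 of them whichever rat was left out and 91 not. Gene results kept their direction and side of the threshold in 286 of 291 with trend and robust shrinkage, 245 of 250 with brighter genes only, 270 of 291 with the mean of probe sets, 128 of 207 with only the groups compared, 257 of 291 with array weights, 284 of 291 with median centring, 282 of 291 with quantile normalization over again, 132 of 291 with the RNA integrity number, 148 of 291 on those 19 arrays without it, 146 of 155 without rat 302 in the shared fit and 252 of 291 without the 3 rats. The other gene results lost or gained a call, and 1 changed sign: Cyp1a1 for smoke without particles, not called, went from -0.07 to 0.12 without rat 102 (limma adjusted p = 0.988), 0.05 without rat 103 (limma adjusted p = 0.993) and 0.09 without rat 205 (limma adjusted p = 0.971), within -0.31 to 0.12 over all rats left out.

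Counts of calls in the fit reported were 127 for smoke without particles, 4 for sand without smoke, 20 for silica without smoke, 184 for smoke under sand, 1 for smoke under silica, 2 for sand under smoke, 2 for silica under smoke, 139 for smoke with sand, 536 for smoke with silica, 1 for the sand interaction, 0 for the silica interaction, 908 for smoke on average, 0 for sand on average, 49 for silica on average and 17 for sand against silica. Those that moved by more than 1.5 times are given below by setting, and the cause was not tested unless stated. With array quality weights they were 1119 for smoke without particles, 201 for sand without smoke, 80 for silica without smoke, 553 for smoke under sand, 250 for smoke under silica, 17 for sand under smoke, 342 for silica under smoke, 1172 for smoke with sand, 2477 for smoke with silica, 54 for the sand interaction, 2651 for smoke on average, 89 for sand on average, 843 for silica on average and 95 for sand against silica. With the RNA integrity number as a covariate, on 19 arrays, they were 42 for smoke without particles, 0 for sand without smoke, 0 for silica without smoke, 10 for smoke under sand, 0 for smoke under silica, 0 for sand under smoke, 0 for silica under smoke, 13 for smoke with sand, 120 for smoke with silica, 0 for the sand interaction, 210 for smoke on average, 2 for silica on average and 0 for sand against silica. On the same arrays without it most of the loss was there already, and they were 46 for smoke without particles, 0 for sand without smoke, 0 for silica without smoke, 21 for smoke under sand, 0 for smoke under silica, 0 for sand under smoke, 0 for silica under smoke, 7 for smoke with sand, 156 for smoke with silica, 0 for the sand interaction, 246 for smoke on average, 6 for silica on average and 2 for sand against silica. With a change of at least 1.5-fold, a stricter limit by construction, they were 79 for smoke without particles, 58 for smoke under sand, 83 for smoke with sand, 224 for smoke with silica, 119 for smoke on average, 15 for silica on average and 5 for sand against silica. With only the groups compared they were 0 for sand without smoke, 2 for silica without smoke, 0 for smoke under sand, 0 for smoke under silica, 9 for silica under smoke, 0 for the sand interaction, 2 for sand on average, 312 for silica on average and 3 for sand against silica. With quantile normalization over again they were 99 for smoke under sand and 1 for sand under smoke, with median centring 3 for sand on average, with brighter genes only 10 for sand without smoke, 0 for sand under smoke and 1 for sand on average, and with the mean of probe sets 3 for smoke under silica, 5 for silica under smoke and 3 for sand on average. Leaving rat 302 out of the shared fit gave 269 for smoke without particles, 42 for silica without smoke, 61 for smoke under silica, 5 for sand under smoke, 66 for silica under smoke, 564 for smoke with sand, 1777 for smoke with silica and 542 for silica on average, and leaving out the 3 rats gave 279 for smoke without particles, 31 for silica without smoke, 3 for smoke under silica, 6 for sand under smoke, 14 for silica under smoke, 376 for smoke with sand, 1 for the silica interaction, 8 for sand on average and 172 for silica on average. With trend and robust shrinkage no count moved by more than 1.5 times.

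With each rat left out in turn, counts ran from lowest to highest as follows, with the rats that moved a count by more than 1.5 times named by number. They ran from 46 to 177 for smoke without particles (57 without 102, 69 without 103, 79 without 105, 46 without 201, 75 without 203, 84 without 204), 0 to 30 for sand without smoke (1 without 102 and 103, 0 without 104 and 304, 30 without 301, 2 without 305), 8 to 20 for silica without smoke (9 without 104, 8 without 105 and 501, 10 without 503), 30 to 703 for smoke under sand (92 without 302, 703 without 305, 37 without 402, 114 without 404, 74 without 405, 30 without 406) and 0 to 16 for smoke under silica (16 without 501, 0 without 502, 503 and 604, 2 without 602, 3 without 605). They also ran from 0 to 7 for sand under smoke (0 without 201, 203, 204, 205, 402, 404 and 406, 7 without 405), 2 to 3 for silica under smoke, 53 to 120 for smoke with sand (53 without 102, 75 without 103, 91 without 104 and 105, 86 without 402, 82 without 404, 54 without 406), 200 to 547 for smoke with silica (259 without 102, 284 without 103, 291 without 104, 323 without 603, 200 without 604) and 0 to 5 for the sand interaction (0 without 102, 103, 305, 203, 204, 205, 402 and 404, 5 without 301, 2 without 302, 3 without 405). For the rest they ran from 0 to 0 for the silica interaction, 586 to 1463 for smoke on average (1463 without 302, 586 without 203), 0 to 6 for sand on average (4 without 301, 5 without 302, 6 without 305, 1 without 203 and 404), 27 to 70 for silica on average (27 without 102 and 204, 28 without 503, 30 without 205) and 7 to 28 for sand against silica (27 without 301, 28 without 304, 9 without 501 and 406, 10 without 502, 504, 402 and 604, 7 without 503, 405, 602 and 603).

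Of 435 list tests 171 passed camera at the preset correlation, 5 with an estimated correlation and 15 in fry. With each rat left out, chosen after seeing the data, 142 to 178 passed at the preset correlation. Correlations across genes of the smoke effect ran, with each rat left out, from 0.343 to 0.492 for none and sand, 0.514 to 0.640 for none and silica and 0.392 to 0.507 for sand and silica, and of the sand and silica effects from 0.151 to 0.619 without smoke and 0.449 to 0.649 under smoke. With the controls split 2 and 2, the sand and silica correlation under smoke fell to 0.121. On arrays, the number of animals and the signal over background of dim probe sets limit the precision of these values.

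For each count the same rats were also put into other groups, and the number of assignments that called at least as many genes, the real one included, was set beside the highest count of any other. This share was 1 of 35 for smoke without particles (127 called against 1) and silica without smoke (20 against 1). It was the same for smoke under sand (184 against 6), smoke with sand (139 against 1) and smoke with silica (536 against 1). It was 1 of 100 for smoke on average (908 against 324) and silica on average (49 against 2). These shares, the lowest possible, argue against chance, with no adjustment over comparisons. So does 2 of 100 for sand against silica (17 against 22), though 1 other assignment called more. Sand without smoke (4 against 1), smoke under silica (1 against 0) and sand under smoke (2 against 0) had 1 of 35 too. The sand interaction (1 against 0) had 1 of 100, but these small counts fell to 0 in limma when 1 rat was left out. Chance could not be excluded for silica under smoke (3 of 35, 2 against 14). Limma called 0 genes for the silica interaction and for sand on average (both 100 of 100, 0 against 1). There was no count to test. For silica under smoke the 14 genes of 1 split may point to structure among these rats other than the exposure, or to chance.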

Other observations

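Chosen only after the result was seen were the reruns of the tests without rats 302, 104 and 604 and of the list tests without single rats. Single members of several further lists changed with smoke on average (12 rats against 12). Among 9 erythroid genes 2 rose, or 3 adjusted over the list alone, the haem synthesis enzyme Alas2 by 0.38 ± 0.11 and Hemgn by 0.71 ± 0.19 (list adjusted p = 0.00198, or 0.447 with an estimated correlation). The call of Hemgn ended without rat 102, 203, 501, 504, 603 or 604 and that of Alas2 without 15 of the 24 rats, with adjusted p up to 0.0595 and 0.0856. Of 10 mesothelial markers 2 fell, or 3 adjusted over the list alone, the transcription factor Wt1 by 0.52 ± 0.11 and Lrrn4 by 0.43 ± 0.12 (list adjusted p = 0.0606), and the call of Lrrn4 ended without 9 of the rats (adjusted p up to 0.0636). The lipoxygenase Alox15, in the list of 16 mast cell and eosinophil markers, rose by 1.23 ± 0.28, while 4 others fell adjusted over the list alone (list adjusted p = 0.104). Of 24 interferon-stimulated genes the antiviral Rsad2 rose by 0.51 ± 0.13 and Irf9 and Bst2 stood lower at -0.30 ± 0.08 and -0.42 ± 0.12, or 1 rose and 5 fell adjusted over the list alone (list adjusted p = 0.00781, or 0.46 with an estimated correlation). The call of Irf9 ended without rat 204, 406, 504, 603 or 604 and that of Bst2 without 12 of the rats (adjusted p up to 0.0552 and 0.0641), and without the 3 rats neither Irf9 nor Bst2 passed. In the list of 15 antigen presentation genes the protease Ctss rose by 0.38 ± 0.08 and the proteasome subunit Psmb9 fell by 0.43 ± 0.10, at 1 and 3 adjusted over the list alone (list adjusted p = 0.711). Tap2 of that list fell by 0.24 ± 0.07, a call that ended without 18 of the rats (adjusted p up to 0.091).

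Of 23 unfolded protein and amino acid stress genes 2 rose, the serine synthesis enzyme Psat1 by 0.51 ± 0.11 and Mthfd2 by 0.31 ± 0.07, over all genes and over the list alone (list adjusted p = 0.126). Of 24 immediate early genes Klf2, Klf4 and Zfp36 fell and Myc rose, at -0.59 ± 0.10, -0.30 ± 0.06, -0.33 ± 0.09 and 0.29 ± 0.07, or 3 and 3 adjusted over the list alone (list adjusted p = 0.529). Of 17 glucocorticoid and metallothionein genes Mt2A and Sgk1 rose, at 0.54 ± 0.15 and 0.23 ± 0.06, and Errfi1 and Map3k6 fell, at -0.32 ± 0.09 and -0.31 ± 0.09, or 3 each way adjusted over the list alone (list adjusted p = 0.825), with a median of -0.06 and a mean of 0.10. Srebf2 was the only 1 of 18 cholesterol genes to fall, at -0.31 ± 0.09, over all genes and over the list alone (list adjusted p = 0.529), and Dcn the only 1 of 29 matrix genes to rise, at 0.53 ± 0.16, with 0 in limma adjusted over the list alone (list adjusted p = 0.825). Single rats ended several of these calls: 3 rats that of Sgk1 (adjusted p up to 0.0568), 7 that of Mt2A (0.0577), 8 that of Map3k6 (0.06), 9 that of Errfi1 (0.0596), 14 that of Srebf2 (0.0799) and 18 that of Dcn (0.0845). Of 40 proliferation genes Prc1 rose, by 0.48 ± 0.11, the only call over all genes and over the list alone (list adjusted p = 2.02e-07, or 0.453 with an estimated correlation). Smoke rat 604 was higher than its group mates in all 40, 20 of them at least 2-fold, and smoke rat 406 had a list mean of 7.65 against 7.06. Without rat 604 the mean change of the list went from 0.226 to 0.135. The collagen Col1a1 stood at -0.16 ± 0.23 (adjusted p = 0.696). Without rat 302 these counts of rises and falls were 4 and 0 for the unfolded protein list, 3 and 3 for the glucocorticoid list, 2 and 3 for the immediate early list, 0 and 2 for cholesterol, 2 and 2 for matrix and 2 and 0 for proliferation, and those of the antigen presentation and interferon lists 3 and 3 and 1 and 5. Without the 3 rats they were 4 and 0, 1 and 3, 2 and 3, 0 and 1, 1 and 2, 1 and 0, 4 and 2, and 1 and 0 in the same order. Limma called 0 genes of the heat shock (18 genes, list adjusted p = 0.945), smooth muscle (13, 0.814), adipocyte (13, 0.904) and cardiac (25, 0.232) lists, over all genes or over the list alone, in a comparison with 3482 genes at an unadjusted p under 0.05, and 1 cardiac gene rose without the 3 rats. Of the lists that did not pass, the mesothelial one lay lower without rat 102, 104, 203, 302, 501, 502 or 604 (adjusted p down to 0.013), the mast cell one without rat 102, 501 or 605 (0.0217) and the unfolded protein one higher without rat 302 or 501 (0.0421), all at the preset correlation. With it estimated and all rats kept, they stood at adjusted p = 0.447, 0.553 and 0.631. In fry the mesothelial list (adjusted p = 0.0310) and the macrophage, T and NK, NRF2, neutrophil, cytokine and type 1 lists passed. The median and mean of the heat shock list differed in sign, at -0.03 and 0.01.

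Since smoke under silica called 1 gene against 127 without particles, 3 hypotheses were tested. The first was that silica lessens the smoke effect. Over the 908 genes called for smoke on average, the median interaction signed by the direction of the smoke effect was -0.0523 on the log2 scale, and 18 of 100 shuffles of the residuals over the additive model were as low, or -0.0737 and 10 of 100 without rats 302, 104 and 604. The second was that Iraqi sand lessens it, with a median of 0.00325 and 54 of 100 as low, or -0.0672 and 14 of 100 without rat 302, and -0.0582 and 19 of 100 without the 3 rats. The third was that smoke lessens the silica effect, with a median of -0.0694 over the 49 genes called for silica on average and 14 of 100 as low, or -0.0568 and 5 of 100 without the 3 rats. All lay inside the range of the shuffles. That range had been set as the bound that would exclude a lessening, which was wrong: it is wide beside the median smoke effect of 0.299 and silica effect of 0.447, so a small lessening may remain and the 3 hypotheses stay open.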
